A study of Mus musculus with 10 samples.

How the data were processed

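Poly(A) RNA from RAW264.7 cells, a mouse macrophage-like line derived from a virus-induced tumour, was sequenced after culture in medium (5 libraries) or in medium with doxorubicin (5 libraries) for 24 h. Doxorubicin is an anthracycline that traps topoisomerase II on DNA and intercalates between bases. Per the labels' protocols, RNA was enriched on oligo(dT) beads, fragmented and reverse transcribed with random primers, and cDNA fragments were selected by size before amplification. The sources gave 3 different doses. The sample titles named 10 nM, the series design named 100 nM with a remark that 100 nM is the right value, and the dilution in the treatment protocol (0.001% by volume of a 100 mM stock in dimethyl sulfoxide) works out at 1000 nM. No dose was therefore used in any calculation, and the labels named the solvent for the doxorubicin cultures but not for the medium cultures.

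The deposited values were FPKM, that is fragments scaled to transcript length and to the mapped fragments of the library, in 1 column per library, with 22186 genes named by symbol. The genome build was GRCm39, per the submitters' processing notes. The aligner, the quantifier, the annotation and any filter on genes were not given in the sources used here. Each column was matched to its library by the library name in the labels. The deposited FPKM values held no read totals, and low values showed no whole-read steps, so the depth of each library was unknown and no counting interval or detection limit was given. Coordinates were not printed, since the reference annotation at hand used another build. That annotation (GENCODE, mouse release of the earlier build) served only for transcript length and GC content by symbol, which it gave for 9685 of the 9869 genes tested (98.1%).

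Values were analysed as log2(FPKM + 1). Genes with a mean of at least 1 FPKM over the 10 libraries were tested (9869 of 22186; 15731 had a value above 0 in some library). The comparison of doxorubicin with medium used limma 3.58.1 in R 4.3.3 with group as the only term, a mean-variance trend and Benjamini-Hochberg adjustment, at an adjusted p of 0.05. Fold changes are on the log2(FPKM + 1) scale, which understates the change of genes near 1 FPKM. The test, the 29 gene lists, the rule for naming genes and most of the alternative settings were chosen before the data were examined. Genes were named in 3 ways: the 10 largest increases and the 10 largest decreases among genes past the threshold whose 5 doxorubicin libraries all lay on 1 side of the 5 medium libraries, leaving out symbols of predicted gene models (1 of the decreases is not reported here); a fixed set of senescence, cytokine and proliferation genes; and up to 4 members of each list with the smallest adjusted p. Other genes named were chosen after their values were seen, and the text says so.

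Gene lists were tested with camera from limma, two-sided, with a preset inter-gene correlation of 0.01 and adjustment over the 25 lists with at least 5 tested members. The same test with an estimated correlation and fry stood beside it. Tests of lists with libraries left out used the preset correlation only. Counts of members past the threshold are given over all genes tested and adjusted over the list alone. The lists covered p53 targets; secreted cytokines and chemokines and secreted proteases, inhibitors, growth factors and adhesion molecules of the senescence-associated secretory phenotype (SASP); senescence markers; DNA replication; G2/M; DNA damage and repair; histones; interferon response; DNA sensing and NF-kB; macrophage identity, classical and alternative activation; apoptosis; lysosome and autophagy; oxidative stress; integrated stress and unfolded protein response; ribosome biogenesis; mitochondrially encoded genes; cholesterol; glycolysis and hypoxia; antigen presentation; doxorubicin targets and transporters; immediate early genes; osteoclast genes; and markers of neutrophils, lymphocytes, dendritic cells and of fibroblasts, epithelium, endothelium and erythroid cells. Mitochondrially encoded genes were matched to the shorter symbols of the table after those symbols were seen. Mx1, Mx2, Trac and Ighm were not analysed here.

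Both groups carried replicate numbers 1 to 5 in the sample titles. Deviations from the group means of the 2 libraries with the same number correlated at 0.79, 0.70, 0.67, 0.52 and 0.55 for numbers 1 to 5. Libraries with different numbers correlated as closely between numbers 2 and 3 (0.69 for medium 2 with doxorubicin 3 and 0.59 for medium 3 with doxorubicin 2) and between numbers 4 and 5 (0.51 in both directions), and the other pairs of different numbers lay between -0.61 and 0.0029. The values thus show 3 sets (1, 2 with 3, 4 with 5) rather than 5 distinct pairs. Since each same-numbered correlation was above 0.1, the numbers were used as a block, and a fit with the replicate number as a block is given beside a result where it changed a call or moved a count by over 1.5 times. Nothing in the labels says that a number marks a shared culture or day. The block fit treats the 5 numbers as independent. If numbers of the same set are not, its p-values are too small and its counts too high.

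Alternative settings were pseudocounts of 0.1 and 0.5, no filter and a filter at a mean of 5 FPKM, 3 other scalings (equal totals, median-of-ratios factors, quantile normalization), the replicate block, robust empirical Bayes, library quality weights, an exact permutation test per gene, and each library left out in turn. Added after seeing the data were fits without both libraries of number 1, with and without the block, a fit with 3 blocks read from the correlations, and a limma interaction test of whether the effect of doxorubicin differed between numbers 2 and 3 and numbers 4 and 5. The counts were also computed for 100 splits of the 10 libraries into 5 and 5.

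The limma steps were tested on simulated data for this comparison, with 9869 genes of which 200 were changed, in 5 simulations. Without the block, 93% of genes changed by 1 on the log2 scale and 48.4% of those changed by 0.5 were recovered, and 0.423% of calls were false. With the block these were 98.8% and 82%, and 5.44% of calls were false. The simulated values followed the block model itself, with independent errors and the same effect in each number. These shares therefore check the steps and do not give the share of false calls in the real data. Other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.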

Results

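Messenger RNA levels were measured in 10 libraries of RAW264.7 mouse macrophage-like cells, 5 kept in medium and 5 kept in medium with doxorubicin for 24 h. The design has 1 comparison, doxorubicin against medium, and the series title names its question, whether doxorubicin brings about the senescence-associated secretory phenotype (SASP), the set of factors that senescent cells release. The dose is uncertain (10, 100 or 1000 nM by different labels). FPKM values summed to between 338293 and 356111 per library, and 8207 to 9125 of 22186 genes were listed at 0. The labels do not say that the libraries of a group came from separate cultures, so p-values measure only the spread between these samples.

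The 2 libraries of replicate number 1 stood apart from the other 8. The ferritin gene Fth1 had the highest FPKM in each library, with 5.21% of the total in medium replicate 1, 3.88% in doxorubicin replicate 1 and 2.14% to 2.56% in the other 8. Pearson correlations of log2(FPKM + 1) between a library of number 1 and one of numbers 2 to 5 ran from 0.937 to 0.982 (median 0.961), against 0.976 to 0.998 (median 0.991) among the 8 libraries of numbers 2 to 5. Within these 8, libraries of 1 group with numbers 2 and 3 or 4 and 5 were closer (0.998 for medium 2 with 3 and for medium 4 with 5) than the 2 groups within a number (0.994 for number 2 and 0.989 for number 4). The first principal component, with 54.3% of the variance, set both number 1 libraries apart, and the second, with 25.4%, placed each doxorubicin library below the medium library of the same number.

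**Figure D1:**
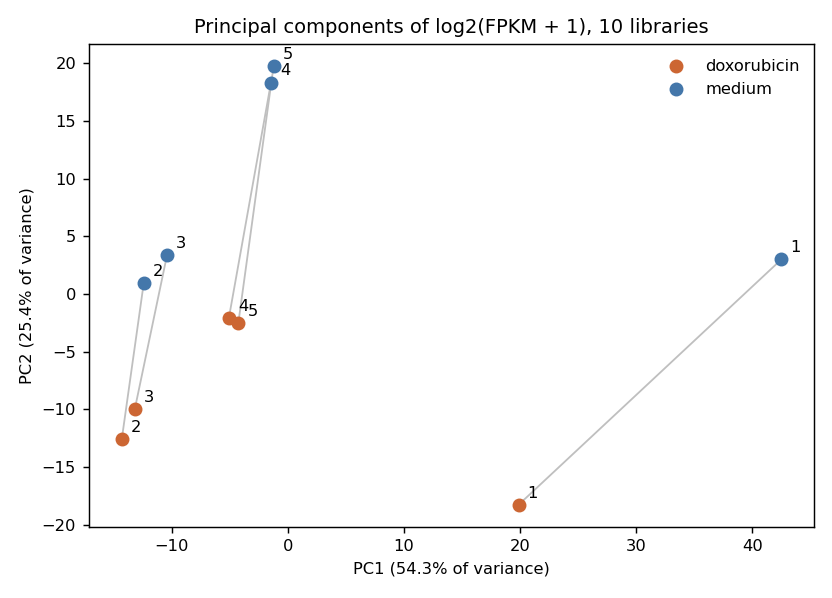
First and second principal components of log2(FPKM + 1) over 9869 genes, in arbitrary units, with 54.3% and 25.4% of the variance. Points are the 10 libraries, coloured by group and marked with their replicate number, and grey lines join libraries with the same number; the 2 libraries of number 1 lie to the right of all others.

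In cells kept with doxorubicin, the largest increases on the log2(FPKM + 1) scale included those of Trp53inp1, a p53-induced nuclear protein gene (1.76 ± 0.282 FPKM in medium and 14.2 ± 8.46 with doxorubicin, SD, n = 5; log2 fold change 2.31, SE 0.28, limma adjusted p = 0.00721), Inka2 (log2 fold change 1.60), Ccng1, which encodes cyclin G1 (36.9 ± 5.49 and 113 ± 32.6 FPKM; 1.56), and Sulf2, an extracellular sulfatase gene (1.49). Cdkn1a, the gene of the cell cycle inhibitor p21, rose from 51.0 ± 4.87 to 147 ± 37.3 FPKM (log2 fold change 1.48, SE 0.14, adjusted p = 0.00466). Zfp365 (1.33), the antiproliferative gene Tob1 (1.28), Phlda3 (1.22), the adenylate kinase gene Ak1 (1.13) and Sbsn (1.13) completed the 10 largest increases. With a pseudocount of 0.1 Inka2 came first among these 10 (2.84 against 2.78 for Trp53inp1). Among genes past the threshold without the replicate block, no fall exceeded 0.61 in size. With the block the largest was that of Trib3 (-2.08). Smg9, a nonsense-mediated decay factor gene, fell by 0.61 on the log2 scale (21.3 ± 3.83 to 13.4 ± 1.39 FPKM, adjusted p = 0.0402), and the other decreases reported were those of Plekhh3 (-0.55), the inner nuclear membrane gene Nrm (-0.54), Mettl22 (-0.52), Apba3 (-0.50), Zfp61 (-0.47), Tmub1 (-0.46), Kptn (-0.45) and Dnajc4 (-0.43).

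In all, 68 of 9869 genes were higher and 22 lower with doxorubicin at a limma adjusted p under 0.05, and 15 were at least 2-fold higher and 0 at least 2-fold lower (1757 genes had an unadjusted p under 0.05, 653 higher and 1104 lower; library quality weights called 21 genes at least 2-fold lower and an exact permutation test 0). All 90 had their 5 doxorubicin libraries on 1 side of the 5 medium libraries, as did 661 of the 9869 genes (6.70%, where chance gives 0.794%). With the replicate number as a block, 771 genes were higher and 1356 lower, 18 and 13 of them at least 2-fold, and without both number 1 libraries 283 were higher and 273 lower. These 2 fits each kept all 90 calls. The count depended on single libraries: it was 226 without medium 1, 57, 45, 15 and 34 without medium 2 to 5, and 49, 53, 33, 24 and 19 without doxorubicin 1 to 5. With any 1 library left out, Trp53inp1, Inka2, Ccng1, Sulf2, Cdkn1a and Tob1 stayed past the threshold, with adjusted p no higher than 0.0328. The other 4 named increases and all 9 named decreases lost it in at least 1 such fit. Mettl22 (highest adjusted p 0.120), Tmub1 (0.126) and Dnajc4 (0.140) lost it in 9 of the 10 fits, and Ak1 (0.137), Smg9 (0.120) and Kptn (0.117) in 8. None of these 19 named genes was called by the exact permutation test, whose smallest possible p of 0.00794 gave adjusted values no lower than 0.118.

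**Figure D2:**
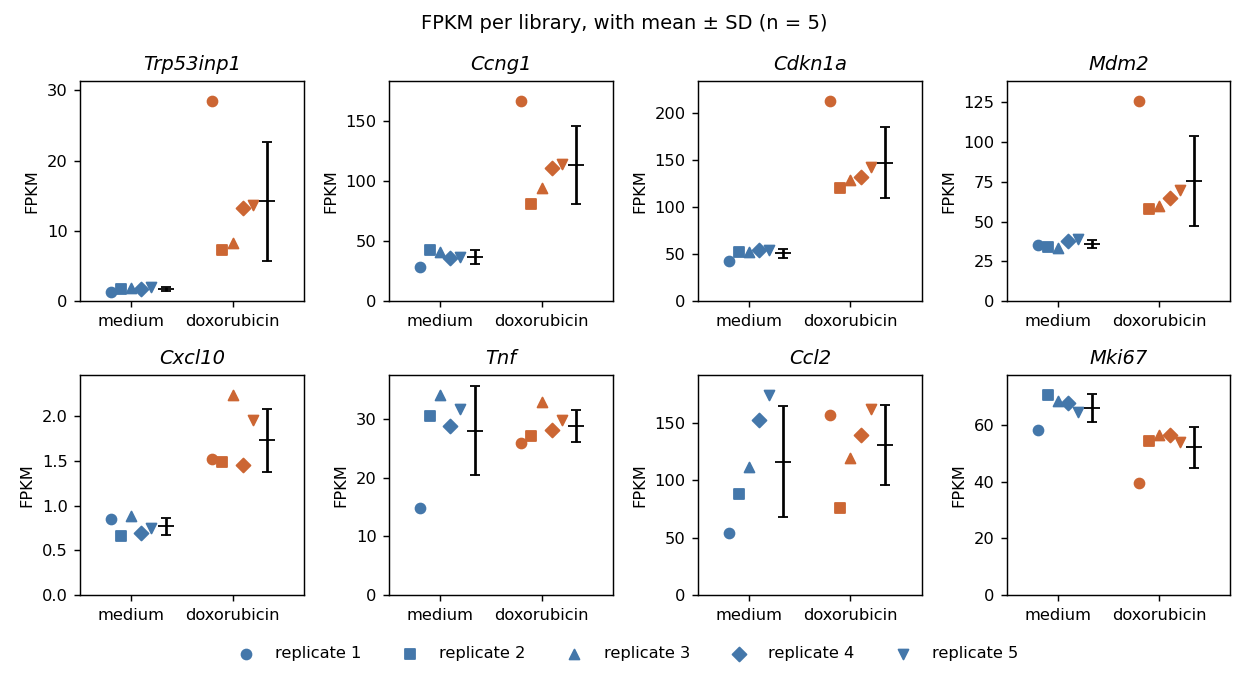
FPKM of 8 genes in each library (linear axes from 0), with points for the 5 libraries of each group, marker shape for the replicate number and black bars for mean ± SD (n = 5). Trp53inp1, Ccng1, Cdkn1a, Mdm2 and Cxcl10 lie higher in the doxorubicin libraries than in any medium library, while the groups overlap for Tnf and Ccl2; Mki67 lies lower in each doxorubicin library than in any medium library but missed the threshold (adjusted p = 0.131, limma).

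Of 31 tested genes known as p53 targets, 11 rose and 20 did not pass the threshold. That is, 11 were higher and 0 lower over all genes tested, and 19 were higher adjusted over the list alone. With the replicate block, 22 were higher and 0 lower. Beside Cdkn1a, Ccng1 and Trp53inp1, the repair endonuclease gene Ercc5 rose from 2.61 ± 0.239 to 5.81 ± 1.59 FPKM (0.89, adjusted p = 0.0154), and Mdm2, whose product targets p53 for degradation, rose from 35.9 ± 2.48 to 75.6 ± 28.4 FPKM (0.99, SE 0.18, adjusted p = 0.0354). The list median was 0.51 (camera adjusted p = 4.75e-17; adjusted p = 0.201 with an estimated correlation), and its median deviation from the other 4 libraries of the group was -0.05 in medium 1 and 0.46 in doxorubicin 1. Within replicate numbers 1 to 5, Cdkn1a differed by 2.29, 1.19, 1.29, 1.26 and 1.38 on the log2 scale, and Mdm2 by 1.79, 0.76, 0.82, 0.75 and 0.83. Without both number 1 libraries, the list had 16 genes higher and a median of 0.38. Trp53 itself stood at 102 ± 20.2 FPKM in medium and 99.2 ± 14.4 with doxorubicin (-0.02, adjusted p = 0.959). Mdm2 missed the threshold without medium 2 to 5 (0.0640, 0.0741, 0.103 and 0.0886) and without doxorubicin 3 to 5 (0.0596, 0.0844 and 0.0917). Rps27l, at 0.521 and 0.762 FPKM, was among genes with the word ribosomal in their names, most of which had low values. The median was 5.47 FPKM for 85 cytosolic ribosomal protein genes, of which Rpl12 was the highest at 42.7.

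Among 18 tested SASP cytokine and chemokine genes, Cxcl10, a chemokine gene induced by interferon, was the 1 gene past the threshold. It rose from 0.768 ± 0.0960 to 1.73 ± 0.352 FPKM (0.62, SE 0.09, adjusted p = 0.0154). Tnf was at 28.0 ± 7.59 and 28.7 ± 2.71 FPKM (0.09, adjusted p = 0.863), Ccl2 at 116 ± 48.4 and 131 ± 34.6 (0.24, adjusted p = 0.746) and Il1a at 2.06 ± 1.34 and 1.68 ± 0.868 (-0.15, adjusted p = 0.834). Il6, with 0.341 ± 0.279 and 0.151 ± 0.119 FPKM, and Il1b, with 0.778 ± 0.432 and 1.03 ± 0.217, lay below the filter and were not tested. Over the list, 1 gene was higher and 0 lower, with the same counts adjusted over the list alone, and with the block 3 were higher, including the interleukin 1 receptor antagonist gene Il1rn (0.90) and Ccl5 (0.75), and 2 were lower, Ccl3 (-0.28) and Ccl4, members of a family of similar copies. The list median was 0.11 (camera adjusted p = 0.106; adjusted p = 0.588 with an estimated correlation), and it was -0.07 without both number 1 libraries. The list passed without medium 5 (0.0416), doxorubicin 2 (0.0242) or doxorubicin 3 (0.0329), and the Cxcl10 call was lost without medium 4 (0.0581) or doxorubicin 5 (0.0536).

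Of 15 tested genes for SASP proteases, inhibitors, growth factors and adhesion molecules, 0 passed the threshold over all genes or adjusted over the list alone (median 0.07, camera adjusted p = 0.243). With the block 4 were higher, among them Icam1, an adhesion molecule gene (0.34), Spp1, the osteopontin gene (0.45), and Timp2 (0.51), and 3 were lower, among them Pdgfb (-0.42). Mmp9 was at 0.908 ± 1.07 and 1.04 ± 1.24 FPKM and was not tested. Of 17 senescence markers, Cdkn1a alone passed over all genes, and adjusted over the list alone 1 was higher and 1 lower (median 0.01, camera adjusted p = 0.243). Cdkn2a was at 3.67 ± 0.351 and 3.71 ± 0.447 FPKM (0.01), Cdkn2b at 7.01 ± 2.36 and 6.41 ± 0.564 (-0.06), the lamin B1 gene Lmnb1 at 63.2 ± 17.3 and 56.5 ± 10.2 (-0.13) and the beta-galactosidase gene Glb1 at 17.7 ± 3.64 and 19.0 ± 2.74 (0.11), with adjusted p of 0.971, 0.904, 0.798 and 0.714. Without both number 1 libraries and with the block, Cdkn2b (-0.25, adjusted p = 0.0457, range over all settings 0.0108 to 0.984) and Lmnb1 (-0.19, 0.0244, range 0.0244 to 0.985) were lower and Glb1 (0.14, 0.0405, range 0.0405 to 0.916) higher. Library quality weights also called Cdkn2b lower. With the block, 1 marker was higher and 3 lower, including Cdkn1b, the p27 gene (8.44 ± 1.92 and 5.12 ± 1.25 FPKM, -0.62).

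**Figure D3:**
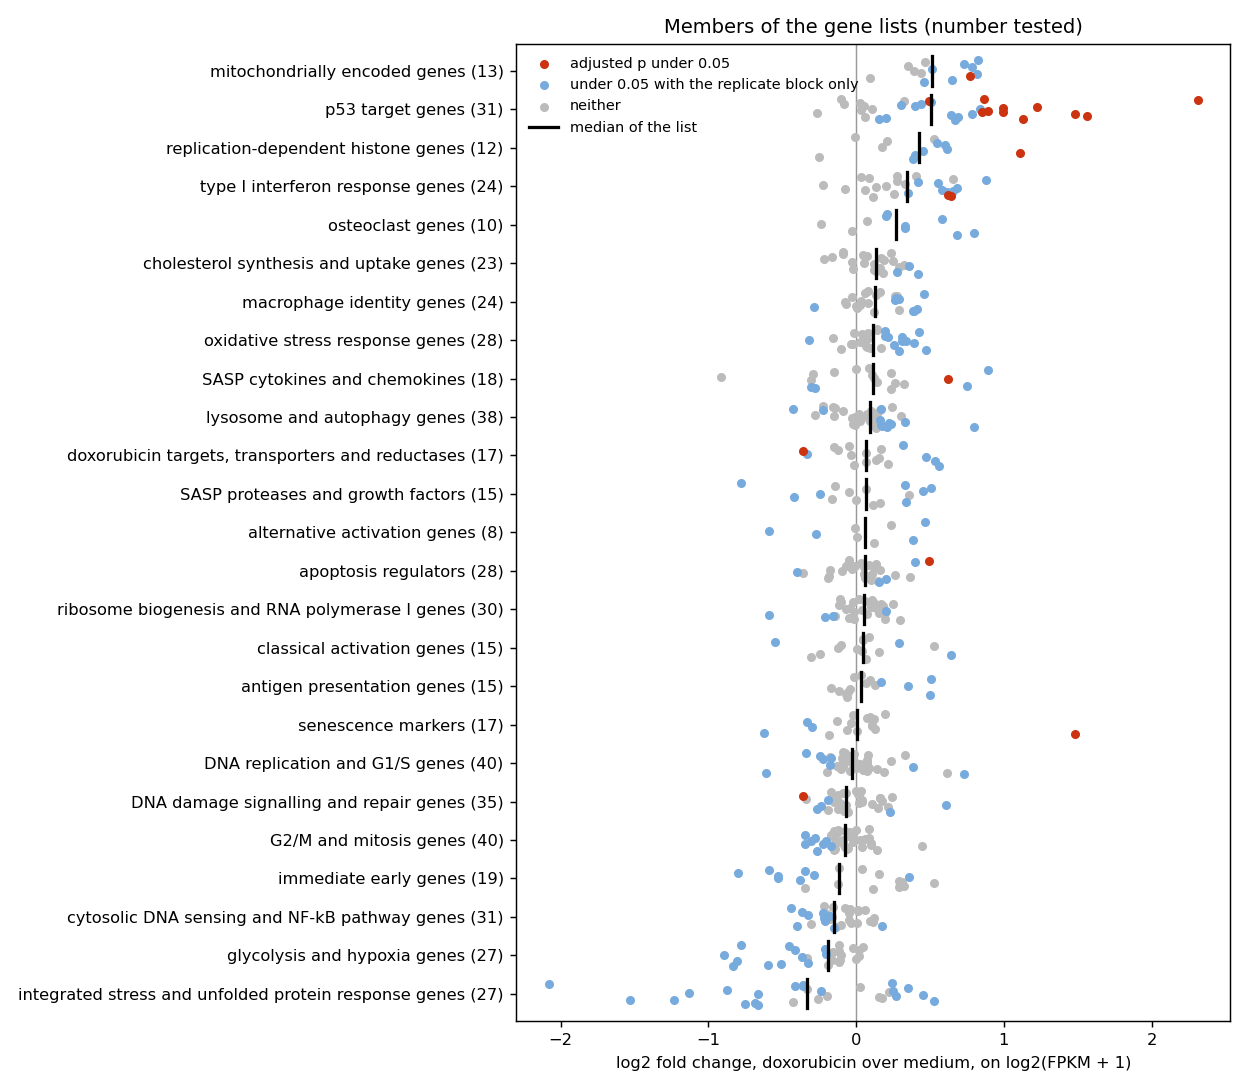
Log2 fold change (doxorubicin over medium, on log2(FPKM + 1)) of each tested member of the 25 gene lists, with black bars at list medians. Points are red where the adjusted p was under 0.05, blue where it was so only with the replicate block, and grey otherwise; p53 targets hold 11 red points and the integrated stress list 0.

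Of 40 DNA replication and G1/S genes, 0 passed over all genes and 1 was lower adjusted over the list alone (median -0.03, camera adjusted p = 0.742). With the block 2 were higher and 6 lower, including Cdc45, a helicase component gene (42.4 ± 7.21 and 27.2 ± 3.17 FPKM, -0.61). Of 40 G2/M and mitosis genes, 0 passed over all genes or adjusted over the list alone (median -0.07, camera adjusted p = 0.116), and with the block 0 were higher and 8 lower. Mki67, a proliferation marker, was at 65.9 ± 4.77 and 52.0 ± 7.16 FPKM (-0.35, adjusted p = 0.131; 0.00617 with the block, and 9.91e-04 to 0.291 over all settings tried) and lay lower with doxorubicin in each of the 5 replicate numbers. Top2a, a target of doxorubicin, was at 86.8 ± 11.5 and 78.0 ± 9.64 FPKM (-0.15, adjusted p = 0.533). It passed with 3 blocks (0.0218) and without both number 1 libraries with the block (0.0302), with a range over all settings of 0.0218 to 0.737. The mitosis list passed without medium 1 (1.53e-04), without doxorubicin 2 (0.0411) and without both number 1 libraries (4.81e-04), and the replication list without medium 1 (0.0231). Of 35 DNA damage and repair genes, 1 was lower over all genes and adjusted over the list alone, Tdp1, which repairs trapped topoisomerase I (17.2 ± 1.08 to 13.2 ± 0.850 FPKM, -0.36, adjusted p = 0.0368); with the block 2 were higher and 4 lower (median -0.07, camera adjusted p = 0.574).

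Among 12 tested replication-dependent histone genes, most of whose transcripts lack a poly(A) tail, 1 passed the threshold. H2bc4 rose from 32.0 ± 4.18 to 71.6 ± 20.6 FPKM (1.11, adjusted p = 0.0154), the 1 gene higher over all genes, against 5 adjusted over the list alone, with 7 higher and 0 lower with the block, including H3c8 (0.55) and H2bc6 (0.45). The median was 0.43 (camera adjusted p = 1.58e-05; adjusted p = 0.392 with an estimated correlation). Its median deviation was 0.29 in medium 1 and 0.58 in doxorubicin 1. Histone genes are near-identical copies, so their values are uncertain where reads were shared, and with no filter on low values the list missed the threshold (0.168).

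Interferon response genes had a median of 0.34 (camera adjusted p = 1.10e-06; adjusted p = 0.392 with an estimated correlation). Of 24 tested, 2 were higher and 0 lower over all genes, Cxcl10 and Cmpk2 (1.13 ± 0.355 to 2.30 ± 0.324 FPKM, 0.65, adjusted p = 0.0480), 5 were higher adjusted over the list alone, and with the block 10 were higher and 0 lower, including Oasl1 (0.42) and the ubiquitin-like gene Isg15 (0.68). The median deviation of this list from the other 4 libraries of the group was -0.96 in medium 1 and -0.52 in doxorubicin 1. Of 31 DNA sensing and NF-kB pathway genes, 0 passed over all genes or adjusted over the list alone (median -0.15, camera adjusted p = 0.182), and with the block 1 was higher, Casp1 (0.18), and 9 were lower, including Nfkbib (-0.18). This list passed as lower without medium 1 (0.0425). It also passed without both number 1 libraries with the block (camera adjusted p = 0.0112, 1 gene higher and 14 lower), but not without the block (0.0708). Of 15 antigen presentation genes, 0 passed over all genes or adjusted over the list alone (median 0.03, camera adjusted p = 0.0743), and with the block 4 were higher, including the invariant chain gene Cd74 (0.50), the peptide transporter gene Tap1 (0.51) and Psmb10 (0.35). The antigen presentation list passed without medium 1 (0.0219) or doxorubicin 2 (0.0242).

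Macrophage identity genes had a median of 0.13 (camera adjusted p = 0.00149; adjusted p = 0.392 with an estimated correlation), and the list deviated by a median of 0.23 in medium 1 and 0.20 in doxorubicin 1. Of 24 tested, 0 passed over all genes or adjusted over the list alone, and with the block 7 were higher and 1 lower, including the lysozyme gene Lyz2 (471 ± 32.7 and 572 ± 74.3 FPKM, 0.27), Laptm5 (0.29), the scavenger receptor gene Cd36 (0.41) and the complement gene C1qc (0.39). Of 10 osteoclast genes, 0 passed over all genes and 2 were higher adjusted over the list alone, and with the block 7 were higher and 0 lower, including Atp6v0d2, a proton pump subunit gene (4.93 ± 1.76 and 9.24 ± 2.26 FPKM, 0.80), the cell fusion genes Ocstamp (0.58) and Dcstamp (0.33), and the cathepsin K gene Ctsk (0.33). The osteoclast median was 0.27 (camera adjusted p = 0.00187; adjusted p = 0.175 with an estimated correlation), and the list deviated by -0.21 in medium 1 and -0.19 in doxorubicin 1. Of 15 classical activation genes, 0 passed over all genes or adjusted over the list alone (median 0.05, camera adjusted p = 0.327), and with the block 2 were higher, Cd80 (0.64) and Ptges (0.29), and 1 lower. Of 8 alternative activation genes, 0 passed over all genes and 1 was higher adjusted over the list alone (median 0.06, camera adjusted p = 0.257), and with the block 2 were higher, including Clec10a (0.38), and 2 lower, including Myc (-0.59). The alternative activation list passed without medium 1 (0.0353).

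A list of 27 tested genes covered the unfolded protein response and the integrated stress response, through which cells answer amino acid shortage and other stresses by way of the transcription factor ATF4. With the replicate block 6 were higher and 13 lower. In a division made after the values were seen, the 6 were among its 10 endoplasmic reticulum genes and the 13 among the other 17. Trib3 was at 57.3 ± 36.0 FPKM in medium and 13.3 ± 9.82 with doxorubicin (-2.08, SE 0.56, adjusted p = 0.114; 1.18e-06 with the block), Atf4 at 259 ± 49.9 and 164 ± 48.2 (-0.68; 7.25e-04 with the block), the asparagine synthetase gene Asns at 155 ± 37.0 and 97.8 ± 24.1 (-0.66; 1.95e-04 with the block) and Mthfd2, a mitochondrial folate enzyme gene, at 130 ± 23.9 and 83.1 ± 22.3 (-0.66; 5.59e-04 with the block). Each of the 4 was lower in 5 of 5 replicate numbers. The size of the effect differed between numbers 2 and 3 and numbers 4 and 5 for 154 of all genes tested, 50 of them with opposite signs (limma interaction test). These included 8 of the 27, Chac1 (-2.09 and -0.40), Ppp1r15a (-0.23 and -1.21), Ddit4 (-0.63 and 0.25) and 5 endoplasmic reticulum genes. The 5 were Calr (0.24 and 0.73), Hspa5 (0.15 and 0.70), Hsp90b1 (0.02 and 0.46), Pdia6 (0.04 and 0.43) and Sdf2l1 (0.05 and 0.50). The interaction test treats numbers 2 and 3, and likewise 4 and 5, as independent, and these sets were read from the same values. If the numbers of a set are not independent, its p-values are too small and its counts too high. Of the 27, 0 passed over all genes and 7 were lower adjusted over the list alone. The median was -0.33 (camera adjusted p = 0.130; 0.0189 with the block, and adjusted p = 0.591 with the block and an estimated correlation), and within numbers 1 to 5 it was 0.02, -0.35, -0.37, -0.35 and -0.33.

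**Figure D4:**
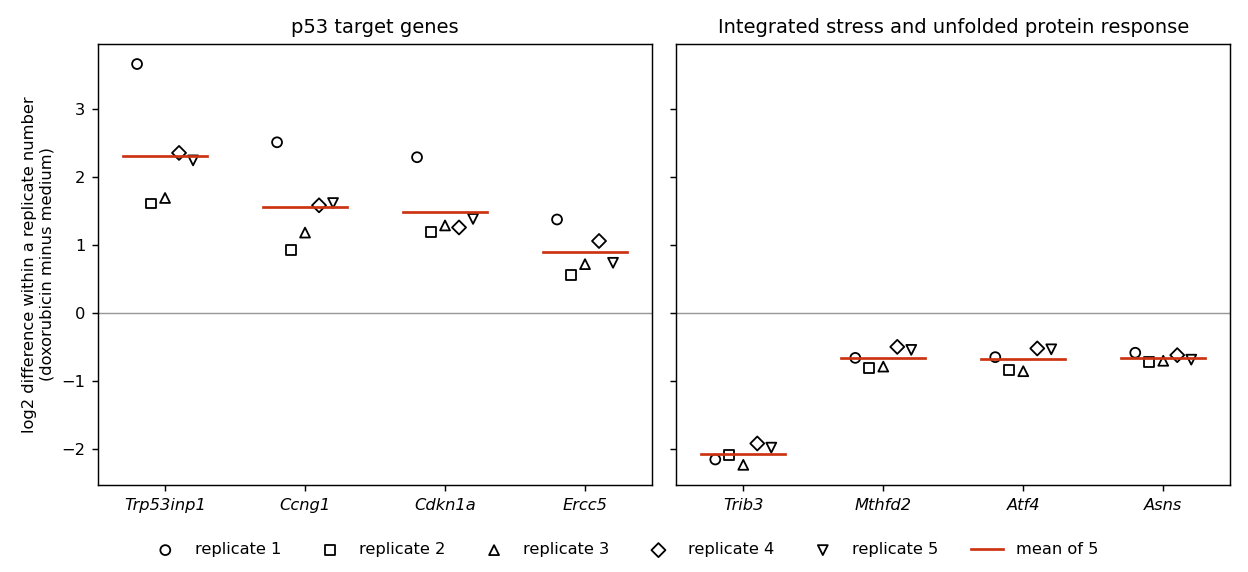
Log2 difference between the doxorubicin and medium libraries of the same replicate number, on log2(FPKM + 1), for the 4 members with the smallest adjusted p of the p53 list (left) and of the integrated stress list (right). Markers are replicate numbers and red lines the mean of 5; Cdkn1a ranges from 1.19 to 2.29 with the highest value in number 1, and each integrated stress gene lies below 0 in all 5.

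Glycolysis and hypoxia genes had a median of -0.19 (camera adjusted p = 0.0242; adjusted p = 0.712 with an estimated correlation). Of 27 tested, 0 passed over all genes or adjusted over the list alone, and with the block 0 were higher and 12 lower, including Ndrg1 (83.6 ± 54.7 and 41.7 ± 19.1 FPKM, -0.90), the oxidase gene Ero1a (-0.81) and Ankrd37 (-0.59). These genes lay above the other 4 libraries of the group by a median of 0.94 in medium 1 and 0.56 in doxorubicin 1. Without medium 1 alone, which leaves doxorubicin 1 in the fit, camera put the list upward but far from the threshold (0.818). Without doxorubicin 2, 3, 4 or 5 it missed the threshold (0.0679, 0.0901, 0.0557 and 0.0515). Without both number 1 libraries the list still passed as lower (median -0.13, camera adjusted p = 0.00736). It also passed as lower with the block (4.57e-05; 0.591 with an estimated correlation), and with the block and without both number 1 libraries (3.08e-04).

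Of 13 mitochondrially encoded genes, 1 passed the threshold. COX2 rose from 26.8 ± 7.82 to 45.3 ± 3.05 FPKM (0.77, adjusted p = 0.0492), the 1 gene higher over all genes, against 11 adjusted over the list alone, and with the block 8 were higher and 0 lower, including ATP8 (0.65), ND4L (0.73) and COX3 (0.82). The median was 0.51 (camera adjusted p = 8.26e-10; adjusted p = 0.392 with an estimated correlation). COX2, ATP8, ND4L and COX3 had 10.1 to 37.2 FPKM in medium against 4296 for COX1 (0.09), and nuclear copies of mitochondrial sequence can share their reads, so these values are uncertain. The list deviated by a median of -0.78 in medium 1 and -0.05 in doxorubicin 1.

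Of 28 oxidative stress response genes, 0 passed over all genes or adjusted over the list alone, and with the block 11 were higher and 1 lower, including the peroxidase gene Gpx1 (323 ± 23.3 and 387 ± 26.8 FPKM, 0.26), the peroxiredoxin genes Prdx1 (0.31) and Prdx2 (0.20), and Cbr3, a carbonyl reductase gene (0.47). Their median was 0.12 (camera adjusted p = 9.55e-04; adjusted p = 0.457 with an estimated correlation), and the list missed the threshold without doxorubicin 1 (0.0874). This list deviated by a median of 0.21 in medium 1 and 0.36 in doxorubicin 1. Of 38 lysosome and autophagy genes, 0 passed over all genes and 2 were higher adjusted over the list alone, and with the block 9 were higher and 2 lower, including Atp6v0d2 and Cd63 (0.24; median 0.10, camera adjusted p = 0.00692; adjusted p = 0.588 with an estimated correlation). The lysosome list missed the threshold without medium 2 (0.110), medium 3 (0.0799) or doxorubicin 1 (0.144), and deviated by 0.30 in medium 1 and 0.26 in doxorubicin 1. Of 23 cholesterol genes, 0 passed over all genes or adjusted over the list alone, and with the block 3 were higher and 0 lower, including Acat2 (0.42) and Hsd17b7 (0.36; median 0.13, camera adjusted p = 0.0242; adjusted p = 0.712 with an estimated correlation). The cholesterol list missed the threshold without medium 4 (0.257), medium 5 (0.403), doxorubicin 2 (0.114) or doxorubicin 3 (0.107), and deviated by 0.18 in medium 1 and -0.11 in doxorubicin 1. Of 28 apoptosis regulators, Tnfrsf10b, a death receptor gene (8.83 ± 0.441 to 13.0 ± 2.21 FPKM, 0.49, adjusted p = 0.0415), was the 1 higher over all genes and adjusted over the list alone, and with the block 4 were higher, including Bax (0.20) and Pmaip1 (0.40), and 1 lower. Their median was 0.06 (camera adjusted p = 0.0242; 0.0735 with the block; adjusted p = 0.427 with an estimated correlation), and the list missed the threshold without medium 2 (0.110), medium 3 (0.0799) or doxorubicin 1 (0.0874). The apoptosis list deviated by a median of 0.02 in medium 1 and 0.17 in doxorubicin 1. Without both number 1 libraries each list of this paragraph passed. Camera adjusted p was 0.00426 for oxidative stress, 2.90e-05 for lysosome, 0.00111 for cholesterol and 0.0305 for apoptosis genes. With the block as well, the apoptosis list missed the threshold (0.0616) and the others passed.

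Of 17 genes for doxorubicin targets, transporters and reductases, 0 were higher and 1 lower over all genes (Tdp1), and adjusted over the list alone 2 were higher and 1 lower (median 0.07, camera adjusted p = 0.0743). With the block 4 were higher, including the drug efflux pump gene Abcb1b (18.2 ± 4.28 and 26.6 ± 1.57 FPKM, 0.56), Xdh (0.32) and Cbr3, and 2 were lower. Of 19 immediate early genes, 0 passed over all genes and 1 was higher adjusted over the list alone, and with the block 1 was higher, Ier5 (0.36), and 7 were lower, including Klf2 (-0.80). Their median was -0.11 while camera put the list upward (adjusted p = 0.587). Of 30 ribosome biogenesis genes, 0 passed over all genes or adjusted over the list alone (median 0.05, camera adjusted p = 0.243), and with the block 1 was higher, Nop16 (0.20), and 3 were lower, including Myc.

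Most markers of other cell types had a mean under 1 FPKM over the 10 libraries and were not tested. Of 11 neutrophil markers, S100a8 alone was tested, at 1.13 ± 0.438 and 1.06 ± 0.193 FPKM (adjusted p = 0.951). Of 13 lymphocyte markers, Cd79b alone was tested, at 5.05 ± 2.22 and 6.04 ± 3.28 FPKM (adjusted p = 0.777), and of 10 dendritic cell markers Batf3 alone, at 8.60 ± 0.944 and 10.6 ± 1.86 FPKM (adjusted p = 0.273). None passed over all genes, and adjusted over the list alone, a list of 1 gene, Batf3 passed. The highest mean among 20 markers of fibroblasts, epithelium, endothelium and erythroid cells was 0.269 FPKM, for Pecam1. Cd79b was highest in replicate number 1, at 8.98 FPKM in medium 1 and 11.9 in doxorubicin 1, against 3.62 to 4.69 in the other libraries.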

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

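The tests of glycolysis genes and of exchanged libraries in replicate number 1 were chosen after the result was seen.

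In 19 of 74 sets of 5 values, 1 library lay farther from the other 4 than Dixon's criterion allows (gap over range above 0.71), where chance gives about 1 in 20, or 3.7. All 19 were in replicate number 1, 9 in medium 1 and 10 in doxorubicin 1. The 74 sets come from the same libraries and are not independent, so 19 against 3.7 is not a test. In medium 1, the lowest values of the group were those of Inka2 (0.203 FPKM, the next being 0.362), Cdkn1a (42.5, next 52.1), Tob1 (4.35, next 7.93), Trp53 (66.8, next 104), Tnf (14.8, next 28.7) and Top2a (66.7, next 88.1). The highest in medium 1 were those of Glb1 (24.1, next 16.9) and Mmp9 (2.81, next 0.586), and the share of Fth1 was 5.21% (next 2.56%). In doxorubicin 1, the highest values were those of Cdkn1a (212, next 143), Tob1 (23.8, next 19.3), Phlda3 (47.0, next 32.1), Ak1 (10.4, next 4.17), Mdm2 (126, next 70.1) and Mmp9 (3.25, next 0.552), and the share of Fth1 was 3.88% (next 2.47%). The lowest in doxorubicin 1 were those of Sbsn (4.43, next 7.95), Trp53 (73.8, next 103) and Mki67 (39.3, next 53.8).

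Both libraries of replicate number 1 stood apart from the other 4 of their group. Across 9869 genes the 2 deviations had a Pearson r of 0.79, but some genes deviated in 1 library alone or in opposite directions (Cdkn1a and Tob1). GC content and transcript length accounted for 0.0297 of the variance across genes of the mean deviation of the 2, which argues against them as its whole cause. An exchange of the 2 libraries between groups is argued against by the p53 targets, whose median difference in number 1, doxorubicin minus medium, was 1.06. By this mean, glycolysis and hypoxia genes lay above the other libraries by a median of 0.75, at percentile 100 of 10000 random lists matched for expression, but other lists were as extreme (p53 targets at 100, DNA replication, G2/M, interferon and ribosome biogenesis genes at 0), so this does not single out a culture with more expression of these genes, and the cause stays open.

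Other groupings of the libraries were examined in 100 splits into 5 and 5, the real one included. The 90 genes past the threshold were matched by 1 split, the real one (highest other 3), and the 15 genes at least 2-fold changed by 1 (highest other 1). This would exclude chance for both counts only if libraries could be exchanged freely. The correlation of same-numbered libraries speaks against that, so these splits do not decide it. Splits that part all 5 replicate numbers number 16, too few for a share under 0.05, and without the block the highest other of them gave 0 genes past the threshold (limma). For the 11 gene lists chance cannot be excluded: 40 of the 100 splits gave as many, and the highest other gave 18. That split set medium 1 to 4 and doxorubicin 2 against the rest. It still parted most libraries by treatment, so its count does not tell treatment from another structure among the libraries. Of the 16 splits that part the replicate numbers, 3 gave as many lists without the block (highest other 12). With the replicate block, 1 of the 16 splits that part all 5 replicate numbers, the real one, gave 2127 genes and the highest other 0, again too few for a share under 0.05. Single lists were as far from 0 in 2 of 100 splits for the p53 targets, 1 for osteoclast genes, 2 for integrated stress genes, 2 for mitochondrially encoded genes, 3 for histones, 8 for interferon genes and 10 for macrophage identity genes. They were as far from 0 in 19 for apoptosis, 30 for lysosome, 32 for oxidative stress, 35 for cholesterol and 42 for glycolysis and hypoxia genes, and in 56 for SASP cytokines. These splits ignore the replicate numbers. Among the 16 that part them, too few for a share under 0.05, cholesterol genes were as far from 0 in 4 and macrophage identity and oxidative stress genes in 2. SASP cytokines were so in 7, and each of the other 9 lists in 1, the real split.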

How the results depend on the processing

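Fits without replicate number 1 and with 3 blocks were chosen after seeing the data. Depth was unknown, so no limit from counting was set. Over all alternatives, 568 results for named genes kept direction and side of the threshold, 132 lost the threshold, 11 gained it and 24 reversed; for lists these were 541, 46, 20 and 17. The replicate block ended the call of the apoptosis list and gave one to the integrated stress list, and it changed no other list call. Scaling left 73.1% to 78.6% of called genes higher (75.6% as reported). The exact permutation test gave 0 genes because its smallest possible p (0.00794) leaves an adjusted p of 0.118 at best (1764 genes had an unadjusted p under 0.05). For the other changes the cause was not tested, with some exceptions. A filter at a mean of 5 FPKM tests fewer genes, and a smaller pseudocount widens low fold changes. Fits with libraries left out use fewer libraries, but calls rose from 90 to 226 without medium 1 and to 556 without both number 1 libraries. The cause of these rises was not tested.

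Genes higher (68) numbered 40 with the mean filter of 5 FPKM, 771 with the block, 1379 with quality weights, 0 by permutation, 283 without number 1, 1010 without it and with the block, 1205 with 3 blocks, and 15 to 136 with 1 library left out. Genes lower (22) numbered 1356, 2302, 0, 273, 1817, 1963 and 0 to 90 under the same settings from the block on. Genes at least 2-fold higher (15) numbered 27 and 23 with pseudocounts of 0.1 and 0.5, 9 with the mean filter, 0 by permutation and 6 to 17 with 1 library left out. Genes at least 2-fold lower (0) numbered 13 with the block, 21 with weights, 15 without number 1 and with the block, and 13 with 3 blocks. Lists called (11) numbered 0 with an estimated correlation and 2 by fry. The lists called by fry were the p53 targets and the osteoclast genes (fry adjusted p = 0.0207 for each). With the block fry called the osteoclast genes (0.00501) and the integrated stress genes (0.0180), and the p53 targets missed the threshold (0.0590).

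Direction reversed for 6 named genes, none past the threshold as reported, where log2 fold changes were at most 0.24 in size (Ccl2). Quality weights gave -0.038 for Cdkn2a, -0.028 for Tnf and -0.093 for Ccl2. Fits without number 1, with or without the block, gave -0.0097, -0.084 and -0.085 for these genes, and median-of-ratios scaling gave 0.0061 for Trp53. With 1 library left out the ranges were -0.029 to 0.044 for Cdkn2a, -0.12 to 0.17 for Tnf, -0.0089 to 0.42 for Ccl2, -0.17 to 0.079 for Trp53, -0.31 to 0.068 for Il1a and -0.22 to 0.053 for Cdkn2b. Adjusted p of lists that reversed was 0.710 for DNA replication, 0.710 for DNA repair, 0.927 for ribosome biogenesis and 0.496 for immediate early genes with weights. For immediate early genes it was 0.786 with the block, 0.742 without number 1 and with the block, and 0.802 with 3 blocks. With 1 library left out it ran from 0.328 to 0.976 for immediate early genes, 0.0231 to 0.843 for DNA replication, 0.162 to 0.948 for DNA repair, 0.0684 to 0.457 for ribosome biogenesis, and 7.88e-05 to 0.818 for glycolysis and hypoxia genes.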

Other observations

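The tests of scaling, of a difference that both groups share, of endoplasmic reticulum genes, of tRNA synthetases and of short transcripts, and the genes named in the next 2 paragraphs, were chosen after the values were seen.

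Beyond the lists, Trex1, which encodes an exonuclease that degrades cytosolic DNA, rose with doxorubicin to 4.39 ± 1.45 FPKM (SD, n = 5; log2 fold change 0.93, limma adjusted p = 0.0383). Sat1, a polyamine acetyltransferase gene, rose from 79.1 ± 11.1 FPKM in medium (0.72, adjusted p = 0.0154), and Slc19a2, a thiamine transporter gene, from 7.15 ± 2.09 to 14.9 ± 0.688 (1.01, adjusted p = 0.0285). Traf4 (0.88) and Psrc1 (0.91) also rose. With the replicate block, Ephx1, an epoxide hydrolase gene (1.45), and Ass1, an arginine synthesis gene (1.13), were higher, and Aqp9, a glycerol channel gene (-1.35), and Gadd45a, a growth arrest gene (-1.11), were lower, each in 5 of 5 replicate numbers, with adjusted p of 0.0977, 0.0893, 0.131 and 0.226 without the block. Some p53 targets did not pass: Gdf15 was at 17.8 ± 9.03 and 21.5 ± 16.9 FPKM (0.11, adjusted p = 0.940), Fas at 7.95 ± 1.47 and 8.28 ± 2.34 (0.03, adjusted p = 0.943) and Bbc3 at 12.6 ± 4.54 and 12.8 ± 3.16 (0.06, adjusted p = 0.927).

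Some genes outside the lists were lower with the replicate block. Pck2, a mitochondrial gluconeogenic enzyme gene, was at 61.9 ± 18.8 and 26.2 ± 9.96 FPKM (-1.24, adjusted p = 0.0736; 2.94e-05 with the block), and Cth (-1.21), Aldh1l2 (-1.17) and Gpt2 (-0.80) were lower in 5 of 5 replicate numbers. Of 20 cytosolic aminoacyl-tRNA synthetase genes, 13 were lower with the block (median -0.29), against 4 of 17 mitochondrial ones (median -0.02). The medians differed by -0.27. These sets were compared after values were seen and their genes are not independent, so a lower amino acid response is neither excluded nor favoured by this difference.

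Members of the integrated stress list outside the endoplasmic reticulum had a median of -0.66, with 13 of 17 lower with the block, while 10 endoplasmic reticulum genes had a median of 0.25, with 6 higher and 0 lower with the block (limma). Scaling as the cause is argued against, since the highest list median under the other 3 scalings was -0.30. The medians of the 2 parts differed by -0.91, but the list was divided after its values were seen, so this speaks for no explanation. With the block 19 of the 27 members passed, 6 higher and 13 lower. That count cannot test a difference between numbers that both groups share. Each number holds 1 library of each group, so such a difference cancels from the comparison on the log2 scale. A state that also differed between numbers, moved by the treatment, cannot be told apart from a separate effect of doxorubicin on this list. Across 200 genes outside it, which are not independent, Pearson r between the difference of numbers 4 and 5 from 2 and 3 and the effect in number 1 was -0.39, and -0.40 over all genes. Over the 27 members it was -0.81, a value computed after the others were seen. Both explanations stay open.

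Most ribosomal protein genes had a low mean FPKM over the libraries, with a median of 5.47 for 85 cytosolic genes (highest 42.7, Rpl12) and 0.720 for 78 mitochondrial ones. The medians were 75.0 for 37 NADH dehydrogenase subunit genes and 96.4 for 39 proteasome subunit genes. Loss of short transcripts is argued against, since 57 respiratory and proteasome genes with transcripts of at most 800 nt had a median of 119 FPKM. Removal of genes with the word ribosomal in their full names before quantification is a candidate explanation: 6 such genes not examined before the test had a median of 0.861 FPKM, against 61.9 for 5 ribosome components without it. In the same direction, 10 kinase genes named after ribosomal protein S6 had a median of 0.141 FPKM, while Rack1, a ribosome component without the word, was at 1435. No biological explanation was tested.

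LOC118568312 was at 2880 FPKM in medium 3 and at 331 to 615 in the other libraries.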
